A study of Homo sapiens with 5 samples.

How the data were processed

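RNA was sequenced in 5 libraries from tumours that grew from HT-29 cells, an established human colon cancer cell line. The cells were implanted under the skin of NOD SCID mice, an immunodeficient strain without T and B cells. Per the labels, the mice were 5-week-old females, 200000 cells were implanted, and rearing lasted 2 weeks on 1 of 4 foods; the same text also speaks of a longer period. The diets were normal food (1 library), food without methionine (2 libraries), food without tryptophan and niacin (1 library) and food without methionine, tryptophan and niacin (1 library, called the combined omission here). Groups and replicate numbers were taken from the treatment label of each sample. The labels do not say whether the pair of methionine-free libraries came from separate mice, so every p-value given here measures only the spread between these samples, which may be technical.

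The deposited files hold expected counts per gene symbol, that is, estimated counts that need not be whole: in each library between 15.2% and 17.6% of the values above 0 carried decimals. Libraries were made with a stranded mRNA kit per the labels' protocols. The submitters' processing notes name the hg19 build, TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18, featureCounts and Subread 2.0.0. The gene annotation, the strand setting of the counting, the treatment of reads with several positions and any step that separated mouse from human reads are not given in the sources used here. Genes that overlap on opposite strands, and genes with near-identical copies, are therefore uncertain. Reads from mouse RNA could have been counted under human symbols, and a low share of such reads would not be seen. No genome coordinates were used, because the reference at hand was of another build than the files.

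The expected counts were rounded to whole numbers before any test. Each file listed 26364 genes, and filterByExpr on the 4 diets kept 10005 and removed 16359. Library totals were 1088084 for normal food, 553502 and 678618 for methionine-free replicates 1 and 2, 613604 for the tryptophan/niacin-free library and 433930 for the combined omission. These totals are shallow. A single count was worth 0.927 CPM, the usual depth-scaled unit, in the deepest and 2.31 CPM in the shallowest library, the floor of 3 counts lay between 2.78 and 6.94 CPM, and at 50 CPM counting error alone was 13.6% to 21.5%. A fold against a count of 0 is given as at least the fold against the floor, which allows for error in the 0 alone, with the lower limit of the exact interval, which allows for error in both counts. Intervals and floors cover counting error only, since PCR copies cannot be recognised in gene counts. TMM factors ran from 0.926 to 1.04.

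The diets formed a layout in which methionine was present or absent and tryptophan with niacin was present or absent. Tests used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3 (quasi-likelihood F-test, TMM scaling, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). A model with 1 mean per diet was fitted to all 5 libraries and gave methionine-free against normal, the combined omission against methionine-free, tryptophan/niacin-free against methionine-free, and the interaction, which is the effect of leaving out methionine without tryptophan and niacin in the food minus its effect with them. That model has 1 residual degree of freedom, from the methionine-free pair, with the spread shared across genes (biological coefficient of variation 0.207, prior degrees of freedom infinite), and every diet with a lone library was assumed to vary like that pair. An additive model with 2 residual degrees of freedom (biological coefficient of variation 0.227) gave the effect of each omission averaged over the other. The comparisons among the 3 lone libraries have no replicate check, and no test of them was made. For these a size rule was set in its place: a TMM-scaled log2 CPM difference (prior count 2) of at least 2-fold, with a 95% exact conditional binomial interval of the count ratio that excludes 1. Such a rule compares a pair of libraries, not a pair of conditions. The methionine-free pair, compared with each other, gave the benchmark for it. SDs are given where a diet had 2 libraries.

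A total of 34 gene lists were fixed, 26 of pathways or gene families and 8 of markers of other cell types that a subcutaneous tumour can hold. In the tested comparisons they were tested with camera of limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 27 lists that had at least 3 tested genes. In every comparison the median log2 fold change of a list was placed as a percentile among 10000 random lists of the same size matched on mean expression, which describes these libraries only. Camera was repeated with an estimated correlation, under which no list passed in any of the 6 tested comparisons. That form of the test has only the 1 or 2 residual degrees of freedom of the fit, so a list could hardly pass. Its values therefore decide nothing about a list. At the preset correlation the test has the opposite limit. It counts genes, taken as nearly independent, and not libraries. A small camera p thus says that the list's genes moved together in these libraries, not that the change would recur in other tumours. Member counts are given adjusted over all genes and adjusted over the list alone.

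The genes named were chosen by a rule. In a tested comparison they are the 10 highest and 10 lowest log2 fold changes past the threshold with a mean of at least 5 CPM and both methionine-free libraries on the same side of the other diet. Where fewer than 10 passed in a direction, the genes with the smallest unadjusted p follow as not past the threshold. In a comparison with no test they are the 10 highest and 10 lowest beyond the size rule with at least 5 CPM in the higher library. The rule adds the 2 to 4 members of each described list with the largest change, and 13 fixed genes: MAT2A, MTR, AHCY, NNMT, NAMPT, NAPRT, QPRT, IDO1, TDO2, WARS1, ASNS, CHAC1 and CD274. Groups, tests, gene lists, the naming rule and the first set of alternatives were fixed before the data were examined.

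Those first alternatives were DESeq2 median-of-ratios size factors, total counts without TMM factors, no filter and a filter at a mean of 5 CPM, DESeq2 1.42.0, limma-voom, robust edgeR, a fit of 3 libraries only, other fold thresholds and prior counts for the size rule, and leaving out libraries in turn. After seeing the data, corrections for each library's trend with transcript length, or with length and GC content, were added. Length and GC content were those of each gene's longest protein-coding transcript in GENCODE release 29, or of its longest transcript where it had no protein-coding one, and were matched by symbol for 95.8% of the genes tested. Each library's trend was fitted with a natural spline over the 8088 matched genes with a mean of at least 20 CPM and was used as an offset. The prior degrees of freedom were then 15.3 with the length and 27 with the length and GC correction, so that an F statistic of the same size gave a higher p. The tests were run on simulated counts with known changes first. With the methionine-free pair against normal, 14.9% of genes changed 2-fold, 67.2% of those changed 4-fold and 93.9% of those changed 8-fold were recovered among 10005 genes. The interaction recovered 2.99%, 10.4% and 50% of the same fold sizes. Between single libraries the size rule recovered 43.3% of 2-fold and 95.5% of 4-fold changes but also took 501 unchanged genes when libraries were simulated to vary like the methionine-free pair. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Tumour size, body weight and metabolites were not analysed here. The result of 1 gene is not reported here.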

Results

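Gene expression was measured by mRNA sequencing in 5 libraries from tumours of the human colon cancer line HT-29. The tumours grew under the skin of immunodeficient mice that ate 1 of 4 foods. There was 1 library from normal food, 2 from methionine-free food, 1 from tryptophan/niacin-free food and 1 from food without methionine, tryptophan and niacin, referred to as the combined omission. Methionine feeds S-adenosylmethionine, the methyl donor with which the enzyme NNMT converts nicotinamide, a product of tryptophan and niacin, into 1-methylnicotinamide, and the design text places the study in that link. The comparisons ask how the tumours differed when each nutrient group was left out, when both were, and whether the effect of leaving out methionine depended on tryptophan and niacin. Totals were between 433930 (combined omission) and 1088084 counts (normal food), and 13750 to 15200 genes had a value above 0. Per the labels, the normal and combined-omission libraries bear titles of a shorter style than the others. A comparison across these styles cannot tell diet from a difference in handling, if the styles mark one.

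The libraries differed most in methionine-free replicate 2. Cytosolic ribosomal protein genes, which have short transcripts, were higher in it than in replicate 1 in 79 of 79 cases (median log2 difference 0.57). The long nuclear noncoding RNAs NEAT1 and MALAT1, picked out after their values were seen, stood at 149 and 80.9 CPM in it against 404 and 223 CPM in replicate 1. When genes were put into 4 equal groups by transcript length, the shortest group (median 1656 bases) had a median log2 difference from the normal library of 0.52 in replicate 2 and the longest (median 7159 bases) one of −0.46. Replicate 1 leaned the same way less, with medians of 0.15 and −0.10 in those groups. The tryptophan/niacin-free and combined-omission libraries stayed within 0.02 of 0. The first principal component (58.8% of the variance) placed replicate 2 at 38.2, replicate 1 at 2.4 and the 3 others between −19.3 and −6.65. Between both methionine-free replicates 660 genes lay beyond the size rule, more than the 352 between tryptophan/niacin-free and normal food or the 202 between the combined omission and normal food. The Pearson correlation of log2 CPM across genes was 0.904 between these replicates.

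**Figure D1:**
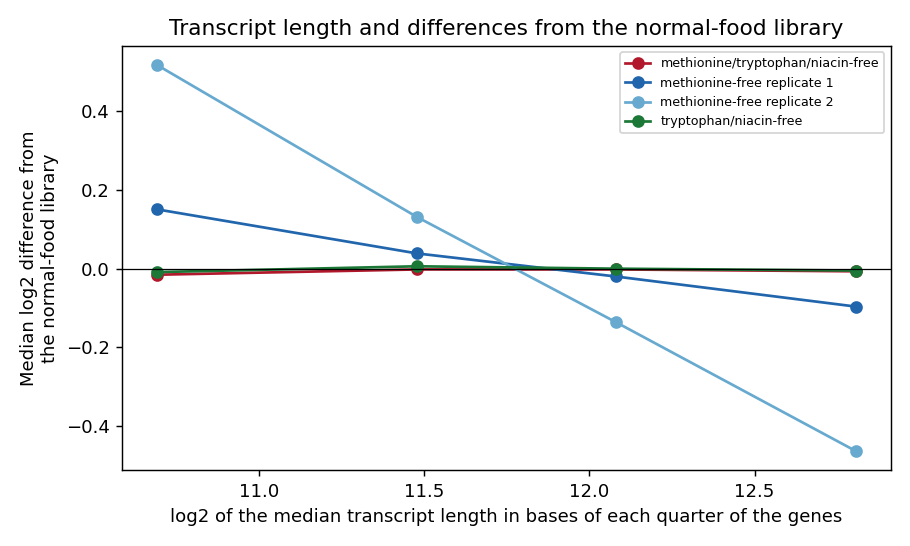
Median log2 difference from the normal-food library (vertical axis) against the median transcript length in bases (log2 horizontal axis) of 4 groups of genes by length, 2022 genes in each, with 1 line per library. Methionine-free replicate 2 runs from 0.516 in the shortest group to −0.463 in the longest, replicate 1 from 0.15 to −0.0965, and the other libraries stay near 0.

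In the methionine-free libraries, several genes induced by low oxygen were below their level on normal food. NDRG1, a stress gene induced by hypoxia, fell from 3368 CPM on normal food to 778 and 649 CPM. VEGFA, the angiogenic growth factor, fell from 685 to 179 and 155 CPM. ADM, which encodes the vasodilator peptide adrenomedullin, fell from 113 to 20.1 and 29.1 CPM, and HK2, a hexokinase that starts glycolysis, fell from 218 to 64 and 48.5 CPM. The gel-forming mucin MUC5B, the transmembrane mucin MUC16 and PIGR, the receptor that carries immunoglobulin A across epithelia, fell as well. PIGR went from 60.2 to 5.48 and 12.9 CPM. MUC16 went from 52.8 CPM to 20.1 in replicate 1 and 1.62 in replicate 2, so that its fall rests mostly on replicate 2. By edgeR's quasi-likelihood test 23 genes were lower and 0 were higher in the methionine-free libraries among 10005. There were 521 lower and 247 higher at an unadjusted p below the same threshold, where 500 in all would pass by chance. Normal and methionine-free libraries differ in title style, so that diet cannot be told apart from a difference in handling.

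The largest falls past the threshold were in HLA-F-AS1 (log2 fold change −4.42, SE 1.14, adjusted p = 0.048), MUC5B (−4.01, SE 0.873, adjusted p = 0.00479) and PIGR (−2.66, SE 0.554, adjusted p = 0.00324). HLA-F-AS1 and MUC5B rest on few counts. MUC5B had 33 counts on normal food and 2 over both methionine-free libraries, a ratio of 17.8 with a counting interval of 4.56 to 153. HLA-F-AS1 had 24 against 1, a ratio of 25.9 (4.23 to 1070). MUC16 (−2.32), the organic cation transporter SLC22A3 (−2.24), NDRG1 (−2.24), ADM (−2.18), the protein kinase A scaffold AKAP12 (−2.17), CCDC183-AS1 (−2.12) and VEGFA (−2.03) followed. Their adjusted p ran from 0.00109 for AKAP12 to 0.0254 for NDRG1 and SLC22A3. HLA-F-AS1 and CCDC183-AS1 are antisense genes whose reads cannot be told from those of their overlapping partners without the strand setting. Among genes not past the threshold, the smallest p in the higher direction belonged to NIP7, a ribosome biogenesis factor (1.84, adjusted p = 0.0676). It was followed by ORMDL2 (1.76), C1GALT1C1 (1.73), POLR2L (1.44), TMA16 (21 counts against 2, a ratio of 9.72 with an interval of 2.38 to 85.5), FAM58A (1.56), MAK16 (2.53), PSME1 (1.34), NDUFAB1 (1.34) and WDR44 (1.72). DESeq2 called 1 gene, NDRG1 (adjusted p = 0.00532), and limma-voom called 22, 18 of them shared. A correction for transcript length, chosen after seeing the data, left 7 genes, 6 of them shared, among them NDRG1 (adjusted p = 0.000284), VEGFA (0.00215), ADM (0.00887) and HK2 (0.0268). It ended the calls of 6 of the 10 largest falls. The fold of MUC16 shrank, to −1.31 (SE 0.541 in place of 0.557, adjusted p = 0.516), and that of MUC5B to −3.41 (SE 0.821, adjusted p = 0.163). For PIGR (−2.54, SE 0.5, adjusted p = 0.0652), HLA-F-AS1 (−4.46), SLC22A3 (−2.22) and CCDC183-AS1 (−2.25) the F statistic rose. Their calls ended because the prior degrees of freedom of the spread went from infinite to 15.3. With length and GC content corrected (27 degrees) these 4 passed, PIGR with an adjusted p = 0.0149, while MUC5B (0.122) and MUC16 (0.417) did not. Total-count scaling ended the calls of HLA-F-AS1 (−4.48, SE 1.17, adjusted p = 0.0552) and PFKFB3 (−1.64, SE 0.432 in place of 0.408, 0.0619), as their SE grew.

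Of the gene lists, the hypoxia and glycolysis list was lowest in the methionine-free libraries, with a median log2 fold change of −0.98 over 23 members, 5 of them above 0 (camera adjusted p = 5.86e-16; adjusted p = 0.915 with an estimated correlation). NDRG1, ADM, VEGFA, HK2, the glycolytic enolase ENO2 (−1.86, adjusted p = 0.00479) and PFKFB3, which makes an activator of glycolysis (−1.58, adjusted p = 0.048; −1.46 and 0.0602 after the length correction), fell, and 11 members did so when adjusted over the list alone. The abundant glycolytic genes GAPDH (3965 CPM on normal food, 3685 and 4249 without methionine) and ENO1 (2066, 1959 and 2317) did not. Colonocyte and goblet cell genes had a median of −0.40 over 18 members (camera adjusted p = 0.00512), with 1 gene lower, MUC5B, and 3 lower adjusted over the list alone. CDHR2 (−2.26, adjusted p = 0.465), ANPEP (−1.81, 0.596) and MUC2 (−1.57, 0.0706) did not pass, although MUC2 did with length and GC content corrected (−1.92, 0.0209). Targets of ATF4, the transcription factor of the amino acid response, had a median of −0.25 over 28 members (0.0129) with 0 past the threshold. The values of NUPR1 (−1.40), DDIT3 (−1.31) and DDIT4 (−1.14) lay below those on normal food, not above, and with length and GC content corrected DDIT3 (−1.85, adjusted p = 0.0253) and DDIT4 (−1.33, 0.0209) passed. Immediate early genes had a median of −0.29 over 16 members (0.0301), with 1 lower adjusted over the list alone (JUN, −1.25) and 0 over all genes. Each of these last 3 lists had an adjusted p = 0.915 with an estimated correlation.

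Cytosolic ribosomal proteins had a median of 0.57 over 79 members, 78 of them above 0 (camera adjusted p = 2.87e-13). The same list separated replicate 2 from replicate 1 by 0.57, and its difference from normal food was 0.20 after the length correction and 0.23 without replicate 2. Interferon response genes had a median of 0.42 over 26 members (0.00694), with IFI44L at 1.46, IFITM3 at 1.04 and ISG15 at 0.95. Their mean log2 CPM was 5.471 on normal food, 5.705 in replicate 1 and 5.884 in replicate 2. Antigen presentation genes had a median of 0.34 over 15 members (0.00694). Adjusted over the list alone 1 was higher, HLA-B (1.29, adjusted p = 0.309 over all genes), beside PSMB8 (1.09) and TAP1 (1.02). In other comparisons, given below, the length correction made the medians of the interferon and antigen presentation lists smaller in size. Cholesterol synthesis and uptake genes had a median of 0.33 over 22 members (0.0354), with IDI1 at 0.97. No member of these 4 lists passed over all genes, although the ribosomal protein gene RPL28 did with length and GC content corrected (1.22, adjusted p = 0.0376), and each list had an adjusted p = 0.915 with an estimated correlation.

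The tryptophan/niacin-free library was compared with the normal library by the size rule. No test was made, and there was no replicate check, as each was a lone library. The libraries also differ in title style, so that a difference in handling cannot be told apart from diet. Hypoxia-induced genes were again among the lowest. NDRG1 stood at 313 CPM against 3368 (log2 difference −3.42), 10.8-fold lower with a counting interval of 9.32 to 12.5. NDUFA4L2, a mitochondrial protein induced by hypoxia, was 8.81-fold lower (4.92 to 17.4), the mitophagy receptor BNIP3L 8.20-fold (4.02 to 19.5), the oxygen-sensing prolyl hydroxylase EGLN3 7.81-fold (3.98 to 17.5) and ADM 7.09-fold (3.72 to 15.1). Genes beyond the size rule numbered 352 of 10005, 251 of them lower, against 86.8 from counting error alone and 660 between the methionine-free replicates.

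Also among the lowest were PPP1R1B, with 1 count against 41 (23.8-fold, 4.04 to 963), GIPR, with 1 count against 27 (15.7-fold, 2.58 to 642), CCDC183 (7.55-fold, 4.54 to 13.5) and PRODH, with 2 counts against 38 (11-fold, 2.85 to 94.4). WDR20, with 0 counts against 21, was at least 4.07-fold lower against the floor of 3 counts, with a counting interval from 3.02-fold. The highest included MYH2, a skeletal muscle myosin, with 15 counts against 0 (at least 8.61-fold higher against the floor, interval from 6.18-fold). They also included the cell cycle transcription factor E2F8 (1.87, count ratio interval 2.03 to 12.3), the immediate early transcription factor EGR1 (1.83, 2.5 to 5.88), DKK1, a secreted WNT antagonist (1.80, 2.64 to 5), FAM89A, with 10 counts against 2 (1.83 to 80.8), GAS2L1 (1.80) and SCEL (1.70). The muscle myosins MYH1, MYH2 and MYH4, near-identical genes, had 13.8, 15.3 and 12 counts in this library and at most 0.83 in any other.

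The hypoxia and glycolysis list had a median of −1.51 here, below all 10000 random lists, with 0 of 23 members above 0 and 14 lower beyond the size rule. Colonocyte and goblet cell genes had a median of −0.60 (percentile 0), 6 of 18 lower, with CDHR2 at −1.97 (1.65-fold to 58.4-fold lower), MUC5B at −1.84, ANPEP at −1.79 (1.41-fold to 51.3-fold lower) and PHGR1 at −1.67. ATF4 targets had a median of −0.21 (percentile 0.36) with 4 of 28 lower, namely DDIT4, an inhibitor of mTOR signalling (−2.58), NUPR1 (−1.76), DDIT3, which encodes the stress transcription factor CHOP (−1.67), and ATF3 (−1.37). Asparagine synthetase ASNS, another ATF4 target, stood at 97.4 CPM against 59.3 (0.69, interval of the ratio 1.14 to 2.37). Proliferation genes had a median of 0.31, above all random lists, with 27 of 33 above 0 and 0 beyond the rule, the highest being the DNA polymerase clamp PCNA (0.90). The methionine cycle list had a median of 0.25 (percentile 98.1) and the NAD and nicotinamide list one of −0.30 (percentile 1.2).

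In the combined omission, hypoxia-induced genes lay nearer to their level on normal food, in a comparison between lone libraries that again had no replicate check. NDRG1 stood at 2367 CPM against 3368 and HK2 at 199 against 218. In all, 202 genes lay beyond the size rule, 95 higher and 107 lower, against 118 from counting error alone. Among the 10 highest were HIRIP3 (log2 difference 2.11, count ratio 6.49, interval 2.17 to 23.2), TMA16 (1.98, from 2 counts on normal food, interval 1.66 to 86.2), GAS2L1 (1.83, 1.95 to 10), the lysosomal amino acid transporter SLC36A1 (1.70, 1.7 to 9.84) and MAK16 (1.68). Among the 10 lowest were INTS2, with 0 counts against 22 (at least 2.94-fold lower against the floor, interval from 2.19-fold), LIN54, with 1 count (13.6-fold, 2.29 to 554), WIPI1, a phagophore protein, with 1 count (8.41-fold, 1.35 to 348) and RUNX2, with 1 count (8.01-fold, 1.28 to 332). The hypoxia and glycolysis list had a median of −0.26 (percentile 0) with 0 members beyond the rule. The methionine cycle list had one of −0.37 (percentile 0.155), with 1 lower, the methionine salvage enzyme APIP (−1.41, 1.14-fold to 12.5-fold lower). Colonocyte genes had a median of 0.16 (percentile 96.6) and amino acid transporters one of 0.13 (percentile 90.9), with SLC38A9, the arginine sensor of the lysosome, at 1.61 (1.37 to 13.9).

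With methionine already absent, leaving out tryptophan and niacin as well went with a rise of 3 genes. MUC5B rose, from 2 counts over both methionine-free libraries to 15, a ratio of 20.2 with a counting interval of 4.7 to 182 (log2 fold change 4.19, SE 0.963, adjusted p = 0.0449). MUC2, the main secreted mucin of the colon, rose from 128 and 37.2 CPM to 354 CPM (2.11, SE 0.426, adjusted p = 0.00711), and the semaphorin receptor PLXNA3 from 143 and 76.1 to 435 CPM (2.00, SE 0.436, adjusted p = 0.0231). By edgeR these 3 genes were higher and 0 lower, with 757 at an unadjusted p below the same threshold. The libraries compared here differ in title style. DESeq2 called 0 genes (37 unadjusted) and limma-voom 9, 2 of them shared. The length correction left 1 gene, NDRG1 (adjusted p = 0.0141), and ended the calls of MUC2 (2.60, SE 0.501, adjusted p = 0.132), PLXNA3 (1.63, SE 0.28, 0.12) and MUC5B (3.60, SE 0.897, 0.284). The F statistic rose for MUC2 and PLXNA3, whose calls ended through the lower prior degrees of freedom (15.3), and fell for MUC5B. With length and GC content corrected MUC2 (2.44, adjusted p = 0.0112) and PLXNA3 (1.36, 0.0444) passed and MUC5B (3.23, 0.244) did not. MUC2 on normal food was at 243 CPM and PLXNA3 at 325 CPM.

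HK2 (1.82, adjusted p = 0.0522), ENO2 (1.73), MZF1 (1.77), PIGR (2.48), MUC5AC (1.72), CEMIP (1.74) and TRIM66 (1.76) came next without passing. HK2 and PIGR passed with total-count scaling (adjusted p = 0.0491 for both), as did NDRG1 (0.0377), and HK2 (0.0474) and ENO2 (0.0425) with length and GC content corrected. In the other direction these were PSMC2 (−1.75, adjusted p = 0.191), DCTPP1 (−1.74), DERA (−1.81), and, with 2 counts each in the combined omission, ARL6IP6 (7.42-fold lower, 1.92 to 63.4) and VRK1 (7.23-fold lower, 1.87 to 61.8). The hypoxia and glycolysis list had a median of 0.67 with 18 of 23 above 0 (camera adjusted p = 1.26e-08). Of its members 0 were higher over all genes and 8 adjusted over the list alone, with PFKFB4 at 2.21 and NDRG1 at 1.73. Colonocyte and goblet cell genes had a median of 0.50 (9.36e-05), 2 of 18 higher and 4 higher adjusted over the list alone. Lower in the combined omission were ribosomal proteins (median −0.58, 0 of 79 above 0, 4.74e-14), interferon response genes (−0.79, 6 of 26 above 0, 0.000167; OAS2 −1.61), antigen presentation genes (−0.50, 2 of 15 above 0, 0.00723) and polyamine metabolism genes (−0.58, 1 of 9 above 0, 0.0201), with 0 of their members past the threshold. The length correction brought these 4 medians to −0.21, −0.41, −0.20 and −0.29. All 6 lists had an adjusted p = 0.686 with an estimated correlation.

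Between both single omissions, tryptophan/niacin-free against methionine-free, no gene passed. These libraries share a title style. The actin regulator DOCK5 (1.70), AKAP12 (1.67) and the kinase MAP3K9 (1.83) had the smallest p in the higher direction. Among those with the smallest p in the lower direction were NDUFA4L2 (−2.26, adjusted p = 0.411), PPP1R1B (1 count against 30, a ratio of 16.1 with an interval of 2.68 to 658), NDUFA11 (−1.74), the goblet cell peptide TFF3 (−1.73), REG4 (−1.62) and IHH (−1.94). edgeR gave 0 genes with 491 at an unadjusted p below the threshold, where chance gives 500, DESeq2 0 (31 unadjusted) and limma-voom 0 (478 unadjusted). The hypoxia and glycolysis list was lower still without tryptophan and niacin, with a median of −0.51 and 0 of 23 above 0 (camera adjusted p = 1.43e-05; 0 lower over all genes, 1 adjusted over the list alone; EGLN3 −1.81). Ribosomal proteins (−0.71, 1.25e-23; −0.29 after the length correction), antigen presentation genes (−0.62, 0.000638; −0.43) and interferon response genes (−0.43, 0.00701; −0.27) had negative medians, and methyltransferases (0.31, 23 of 30 above 0, 0.00305; 0.22 after the length correction and 0.14 without replicate 2) and skeletal muscle markers (0.41 over 3 genes, 0.017) positive ones. These 6 lists each had an adjusted p = 0.765 with an estimated correlation.

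Against the tryptophan/niacin-free library, the combined omission had higher hypoxia-induced and mucus genes. No test was made here either, there was no replicate check, and the libraries differ in title style. NDRG1 was 7.57-fold higher (6.49 to 8.86), NDUFA4L2 7.37-fold (3.93 to 15), PIGR 6.67-fold (2.48 to 22.5) and PPP1R1B, from 1 count, 21.7-fold (3.35 to 915). The counting intervals of the ratio were 3.39 to 9 for HK2, 2.66 to 13.3 for EGLN3, 2.28 to 14.7 for the glycolysis regulator PFKFB4 and 3.07 to 8.62 for DDIT4. Genes beyond the size rule numbered 404, 231 higher and 173 lower, against 142 from counting error alone. Total-count scaling without TMM factors gave 210 and 205. MYH2, NTAN1, INTS2, ZBTB8A and ZNF543 were lower from counts of 0, by at least 3.45-fold for MYH2 to at least 2.3-fold for ZNF543 against the floor, with intervals from 2.47-fold and 1.55-fold. EGR1 was lower as well (log2 difference −1.70). All 23 hypoxia and glycolysis genes were higher, 13 beyond the rule (median 1.41, percentile 100). So were 17 of 18 colonocyte and goblet cell genes, 6 beyond the rule (0.75, percentile 100), among them the mucus protein FCGBP (1.96), ANPEP (1.79, from 2 counts, interval 1.16 to 56) and MUC2 (1.74). Proliferation genes had a median of −0.33 (percentile 0) with 0 beyond the rule. The methionine cycle list had one of −0.27 (percentile 2.66), with APIP at −1.86.

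By edgeR's test, the effect of leaving out methionine differed with and without tryptophan and niacin in the food for 43 genes. Of these, 9 were in the hypoxia and glycolysis list. The spread came from the methionine-free pair alone, and each other diet had a lone library. The test therefore cannot tell an effect of diet from a difference between single tumours, or from one in handling between the differently titled libraries. NDRG1 was at 3368 CPM on normal food and 2367 in the combined omission, against 778 and 649 in the methionine-free libraries and 313 in the tryptophan/niacin-free library. HK2 stood at 218 and 199 CPM against 64, 48.5 and 36.7, and MUC2 at 243 and 354 CPM against 128, 37.2 and 104. DKK1 went the other way, with 55.6 and 76.3 CPM against 133, 134 and 201. By edgeR 42 interactions were positive and 1 was negative, with 645 at an unadjusted p below the threshold. The smallest adjusted p was 1.21e-06, for HK2 (log2 4.39, SE 0.681).

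The highest interactions were those of MUC5B (log2 6.42, SE 1.28, adjusted p = 0.000398), PIGR (5.37, adjusted p = 2.43e-05), the erythropoietin receptor EPOR (5.32, 0.0369), PPFIA4 (5.27, 0.0404), NDRG1 (5.16, SE 0.909, 2.43e-05), PPP1R1B (4.85, 0.028), HK2, ADM (4.34, 2.43e-05), CCDC183 (4.18, 6.3e-06) and ENO2 (4.08, 6.3e-06). MUC5B, EPOR, PPFIA4 and PPP1R1B had 3 counts or fewer in a diet, so that their fitted values depend on the prior count. For EPOR the count ratio to the methionine-free pair was 6.48 on normal food (1.89 to 34.4) and 12.6 in the combined omission (3.51 to 68.3), and for PPFIA4 the ratio of the combined omission to the tryptophan/niacin-free library was 7.25 (1.54 to 68). DKK1 was the gene with a negative interaction (−2.66, SE 0.68, adjusted p = 0.028). Next on that side, without passing, came EGR1 (−2.39, adjusted p = 0.141, or −2.53 and 0.0386 with length and GC content corrected), E2F8 (−3.41), PCNA (−2.08) and DEPDC1B (−2.70). DESeq2 called 2 genes, NDRG1 (adjusted p = 6.25e-10) and VEGFA (0.0153), with 63 unadjusted, so that HK2 (0.0754) and the other calls were lost, and limma-voom called 42, 36 of them shared. The length correction ended the calls of EPOR (5.41, SE 1.27 in place of 1.4, adjusted p = 0.11), PPFIA4 (5.06, SE 1.32 in place of 1.4, 0.176) and PPP1R1B (5.08, SE 1.09 in place of 1.24, 0.0635). Their F statistics rose, so that these calls too ended through the lower prior degrees of freedom (15.3). With length and GC content corrected PPP1R1B passed (0.0363), and EPOR (0.0569) and PPFIA4 (0.129) did not. Total-count scaling ended the call of DKK1 (−2.62, adjusted p = 0.0593), as its SE grew to 0.721. In simulated counts, the interaction recovered 50% of 8-fold and 10.4% of 4-fold changes.

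**Figure D2:**
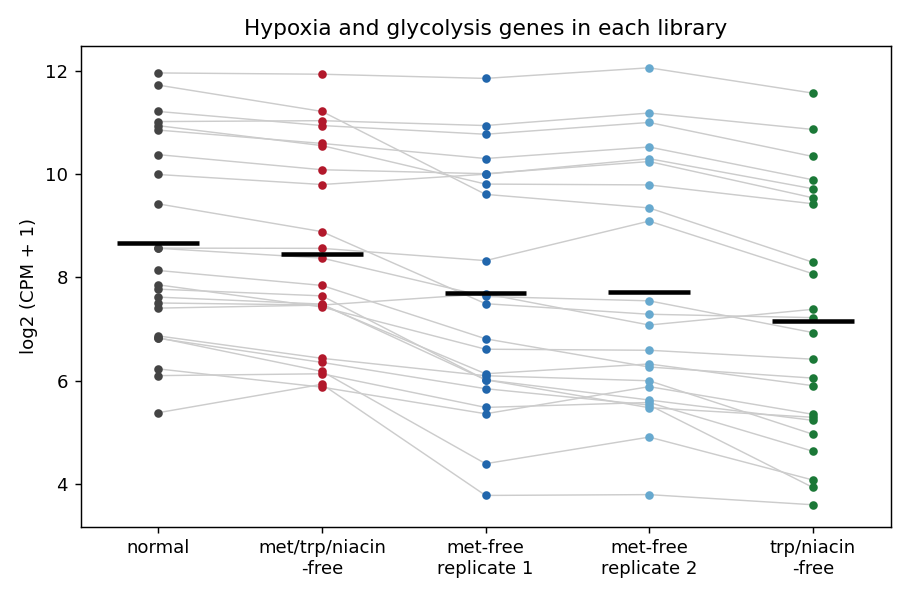
Expression of the members of the hypoxia and glycolysis list in each library as log2(CPM + 1), with 1 point per gene and a black bar at the mean of the list. The normal and combined-omission libraries lie above the 3 others, as for NDRG1 with 3368 and 2367 CPM against 313 to 778 CPM.

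The hypoxia and glycolysis list had a median interaction of 2.28 with 22 of 23 members above 0 (camera adjusted p = 4.44e-34; adjusted p = 0.749 with an estimated correlation), 9 of them higher over all genes and 14 adjusted over the list alone. Its mean log2 CPM was 8.67 on normal food and 8.46 in the combined omission, against 7.73 and 7.75 in the methionine-free libraries and 7.22 in the tryptophan/niacin-free library. The normal and combined-omission libraries were also the pair whose labels bear titles of a shorter style than the 3 others. Colonocyte and goblet cell genes had a median of 1.03 with 15 of 18 above 0 (2.21e-09), with MUC5B, MUC2 (3.34, adjusted p = 0.000398) and FCGBP (2.84, adjusted p = 0.012) higher over all genes and 5 adjusted over the list alone. ATF4 targets had a median of 0.46 with 17 of 28 above 0 (0.0158), with DDIT4 (3.47, adjusted p = 0.000386) and DDIT3 (3.04, adjusted p = 0.0443) higher and 3 adjusted over the list alone. Proliferation genes had a median of −0.61 with 5 of 33 above 0 (0.000822), interferon response genes −0.55 with 4 of 26 (0.0103), polyamine genes −0.78 with 1 of 9 (0.033) and ribosomal proteins −0.41 with 2 of 79 (0.000137; −0.07 after the length correction). The 3 skeletal muscle markers had a median of 1.40 and a mean of −0.64, of opposite sign (0.025), beside the myosin counts of the tryptophan/niacin-free library. The adjusted p of these lists was 0.749 with an estimated correlation, and that of the ribosomal proteins 0.843. The small camera p at the preset correlation count genes and not tumours, and most diets here had a lone library.

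Averaged over the other omission, neither nutrient group gave a gene past the threshold. For methionine left out, HIRIP3 (2.15), C1GALT1C1 (1.39) and the immunoproteasome subunit PSMB8 (1.06) were among the genes with the smallest p in the higher direction and ALS2CL (−1.41), AKAP12 (−1.36) and SPIDR (−1.12) in the lower. For tryptophan and niacin left out these were GAS2L1 (1.58), TNS4 (1.03), CHORDC1 (1.25), PDCD11 (1.01) and the chaperone HSPH1 (0.83). In the lower direction they were PHGR1 (−1.89), the fatty acid oxidation enzyme HADH (−1.19), PRAP1 (−1.66) and ECM1, which had 2 and 1 counts in those libraries. edgeR gave 0 genes for both, with 173 and 163 at an unadjusted p below the threshold and a smallest adjusted p of 1. DESeq2 gave 0 and 0 (23 and 22 unadjusted), and limma-voom 0 and 0 (177 and 147 unadjusted). The hypoxia list, whose interaction passed, had averaged medians of −0.06 for methionine (camera adjusted p = 0.975) and −0.18 for tryptophan and niacin (0.0805).

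Ribosomal proteins had a median of 0.38 for methionine left out (79 of 79 above 0, camera adjusted p = 6.61e-15) and one of −0.39 for tryptophan and niacin left out (0 of 79 above 0, 6.79e-17), and after the length correction 0.16 and −0.15. Antigen presentation genes had medians of 0.26 (12 of 15 above 0, 0.0152) and −0.36 (0.00366) in the same comparisons, and after the length correction 0.16 and −0.24. For tryptophan and niacin left out, interferon response genes had a median of −0.29 (0.00148), amino acid transporters 0.26 with 13 of 15 above 0 (0.00366; SLC36A1 1.47, SLC38A9 1.05) and methyltransferases 0.19 (0.0233). The mean log2 CPM of methyltransferases was 6.274 without tryptophan and niacin and 6.197 in the combined omission. It was 6.171 on normal food, 6.081 in methionine-free replicate 1 and lowest in replicate 2, at 5.788. With an estimated correlation the 2 lists for methionine had an adjusted p = 0.963 and the 5 for tryptophan and niacin an adjusted p = 0.864.

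**Figure D3:**
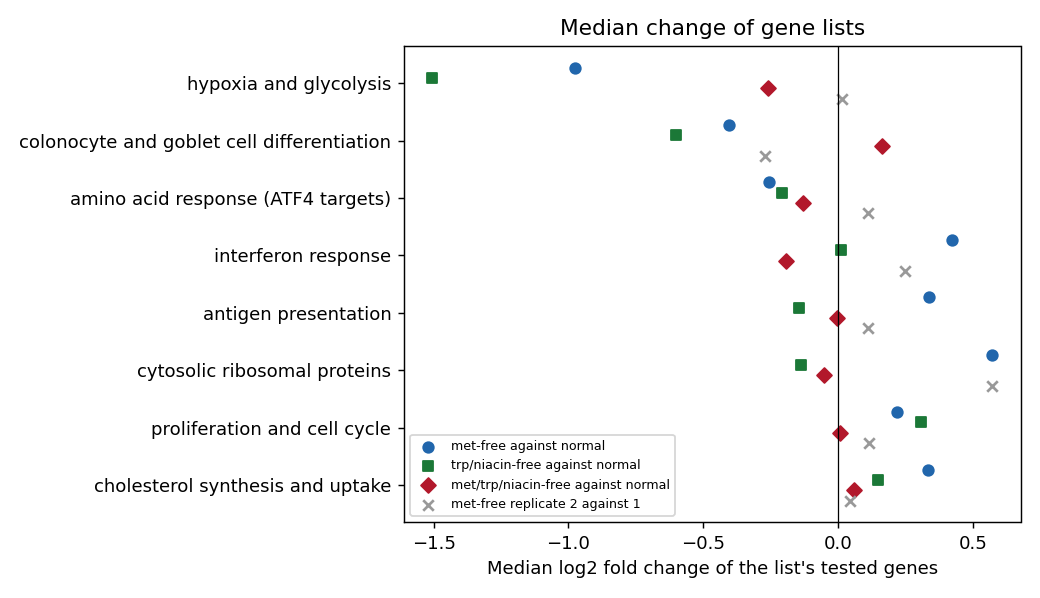
Median log2 fold change (horizontal axis) of 8 gene lists for methionine-free, tryptophan/niacin-free and combined-omission libraries against normal food, and for methionine-free replicate 2 against replicate 1. The hypoxia and glycolysis list lies at −0.98, −1.51 and −0.26 in the comparisons with normal food and at 0.01 between the replicates, while ribosomal proteins lie at 0.57 both for methionine-free against normal food and between the replicates.

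Enzymes of the link between methionine and nicotinamide did not pass in any tested comparison. MAT2A, which makes S-adenosylmethionine, stood at 485 CPM on normal food, 458 and 371 in the methionine-free libraries, 579 without tryptophan and niacin and 518 in the combined omission (methionine-free against normal −0.23, adjusted p = 0.957). AHCY, which clears the product of methylation reactions, stood at 348 CPM on normal food and 614 ± 145 (SD, n = 2) without methionine (0.82, SE 0.486, adjusted p = 0.75). Methionine synthase MTR stood at 55.6 against 62.1 and 27.5 CPM (−0.33, adjusted p = 0.917, and above 0 after the length correction). NNMT had few counts, 9 on normal food, 6 and 9 in the methionine-free libraries, 5 without tryptophan and niacin and 1 in the combined omission. It was not tested. The count ratio of the combined omission to the methionine-free pair was 0.18 (0.00427 to 1.17) and the intervals of the other pairs of diets held 1 as well, so that a difference was not detectable at this depth. The NAD salvage enzyme NAMPT stood at 102 CPM on normal food and at 71.7 to 92.2 CPM in the other 4 libraries (methionine-free against normal −0.24, adjusted p = 0.939). The niacin-using enzyme NAPRT stood between 225 and 288 CPM. QPRT, which uses the tryptophan product quinolinate, stood between 30.3 and 57.8 CPM and the tryptophanyl-tRNA synthetase WARS1 between 67.7 and 87.4 CPM. The tryptophan-degrading enzyme IDO1 had 1 count in methionine-free replicate 1 and 0 elsewhere, and TDO2 had 0 in all libraries. The checkpoint ligand CD274 had at most 1 and CHAC1, an ATF4 target, at most 8.

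The remaining lists did not pass in methionine-free against normal food. Their medians were 0.05 for methionine cycle and salvage (13 members, camera adjusted p = 0.851, with a mean of −0.01 of opposite sign), 0.32 for transsulfuration (11, 0.502), 0.36 for polyamines (9, 0.113), and 0.30 for folate metabolism (14, 0.216). Without methionine-free replicate 2 transsulfuration had a median of −0.14 and folate metabolism one of −0.05, and after the length correction these were 0.14 and 0.13. The mean log2 CPM of polyamine genes was 7.031 on normal food, 7.181 in replicate 1 and 7.465 in replicate 2. The medians against normal food were 0.23 for aryl hydrocarbon receptor targets (4, 0.851) and −0.13 for NAD and nicotinamide metabolism (13, 0.817). Tryptophan and kynurenine genes had a median of −0.15 (7, 0.885) while the test pointed up. Medians were −0.19 for methyltransferases (30, 0.109), −0.01 for amino acid transporters (15, 0.817), 0.22 for proliferation (33, 0.0595), and 0.35 for NRF2 targets (18, 0.125). They were 0.14 for checkpoint ligands (9, 0.851), −0.01 for WNT targets and stem cell genes (11, 0.817) and −0.27 for mesenchymal transition (7, 0.502). The mean log2 CPM of NRF2 targets was 6.664 on normal food, 6.654 in methionine-free replicate 1 and 7.076 in replicate 2. Their rise thus lay in replicate 2 alone. Fatty acid synthesis genes had a median of −0.04 and a mean of 0.01 (9, 0.88), and genes of the unfolded protein response a median of 0.00 (16, 0.851). Autophagy and lysosome genes had a median of −0.05 (16, 0.851), with 1 lower, the autophagy-starting kinase ULK1 (−1.79, adjusted p = 0.00952; −1.63 and 0.0596 after the length correction). Of replication-dependent histones only 1 gene could be tested, and their summed level was 62.1 CPM on normal food, 76.7 and 108 without methionine, 63.8 without tryptophan and niacin and 102 in the combined omission.

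Counts of markers of other cell types were scarce under human symbols. Host cells in these tumours are mouse cells, and how mouse reads were treated is not known. The counts therefore do not show that such cells were few. Of 19 fibroblast markers 11 had no count in any library, as did 8 of 13 endothelial, 13 of 19 macrophage and neutrophil, 12 of 13 lymphocyte, 3 of 9 adipocyte, 2 of 13 skeletal muscle, 6 of 10 keratinocyte and 7 of 7 red blood cell markers. The fibroblast list (3 tested genes) had a median of 0.38 and a mean of −0.04 in methionine-free against normal food (camera adjusted p = 0.851), and the skeletal muscle list (3) a median of −0.61 (0.0667). The other lists had 0 to 2 tested genes. Summed fibroblast markers stood between 101.9 and 150 CPM and skeletal muscle markers between 44.5 and 116.8 CPM. Summed endothelial markers stood between 48.5 and 84.1 CPM, adipocyte markers between 28.3 and 42.8 CPM and keratinocyte markers between 25.5 and 44 CPM. Lymphocyte markers reached 1.85 CPM on normal food and 0 elsewhere, and red blood cell markers were at 0. Macrophage and neutrophil markers summed to 2060 to 3785 CPM, nearly all from LYZ, a lysozyme gene that intestinal epithelium can also express.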

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

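Of the tests below, the correction for transcript length and GC content and the comparison of title styles were chosen after the results were seen, while the thinning to equal depth was set before its value was seen.

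The effect of leaving out methionine differed with and without tryptophan and niacin in the food for 43 genes by edgeR's test of the interaction itself. Their interactions on the log2 scale were 6.42 for MUC5B, 5.37 for PIGR, 5.32 for EPOR, 5.27 for PPFIA4, 5.16 for NDRG1, 4.85 for PPP1R1B, 4.39 for HK2, 4.34 for ADM, 4.18 for CCDC183 and 4.08 for ENO2 among the highest. Those of list members that passed were 3.47 for DDIT4, 3.04 for DDIT3 and 3.34 for MUC2, and DKK1 had the negative one, −2.66.

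Of the genes with a called interaction, 9 were in the hypoxia and glycolysis list. The mean level of that list was higher in the normal and combined-omission libraries than in the 3 others. This pattern had a gap of 0.71 log2 units between the lower of the pair and the highest of the rest. Trends with transcript length and GC content are argued against as its cause, since the median interaction of the list was 2.28 before and 2.06 (SE 0.406) after correcting for both, above the bound of 1.14 under which these trends would have been the cause. That SE was taken across the list's genes, which are not independent replicates, and may be too small. Sequencing depth is also argued against, though not by thinning. The gap was 0.721 when every library was thinned to 425010 counts, but thinning keeps each gene's share and could hardly move it. The higher pair held the deepest library (normal food, 1088084 counts) and the shallowest (combined omission, 433930). A level that followed depth would not put these together, a reading added after the values were seen. A difference in handling remains open and cannot be told apart from diet, as the pair with the higher level also bears the shorter titles and no diet has libraries of both styles, and an exchange of labels between the combined-omission and tryptophan/niacin-free libraries, which would change what the interaction means, was not tested and stays open, since the labels give nothing to check it by. Diet itself stays open as well, as untested: each level other than the methionine-free one rests on a lone tumour, whose size, oxygen supply and site of sampling might differ by chance.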

How the results depend on the processing

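The corrections for transcript length and for length with GC content were chosen after the results were seen; the other alternatives were set before. Signs were compared for named genes and list medians only. The alternatives compared were DESeq2 size factors, total counts, both trend corrections, leaving out a methionine-free replicate and, for genes, the DESeq2 test. No named gene or list past the threshold changed sign under these, but several lists and genes that were not past it did. Over all alternatives 77 counts of genes or lists stayed within 1.5 times their reported value and 36 did not. Of the list medians 788 stayed within the spread and 400 moved further. Of the values of named genes 2707 stayed on their side of the threshold or within the spread, 45 no longer passed, 12 passed only under the alternative and 155 moved beyond the spread or, short of the threshold, changed sign. The 2707 include values of genes that had not passed and so had no call to lose. They are no measure of how stable the calls were. Of the 45 lost calls, 26 were lost with the DESeq2 test. For the changed counts that follow, the cause was not tested except where stated. No paired analysis was possible because 3 of the 4 diets had 1 library each, so that no pair of diets shared 2 replicate numbers.

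For methionine-free against normal food, 23 genes became 1 with DESeq2, 7 with the length correction (6 of them shared) and 37 with the length and GC correction (17 shared). For the combined omission against methionine-free food, 3 genes became 0 with DESeq2, 9 with limma-voom (2 shared), 6 with total counts (3 shared), 1 with the length correction (0 shared) and 7 with the length and GC correction (2 shared). The 43 interactions became 2 with DESeq2 and lay between 35 and 61 under the other alternatives, 30 of them shared with the length correction and 37 with length and GC. With an estimated correlation the 8, 6, 6, 8, 2 and 5 lists past the threshold in the 6 tested comparisons became 0 in each. The 1 or 2 residual degrees of freedom of that form of the test made this outcome near certain.

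For the averaged effects, leaving out a lone library removes a whole diet and leaves a comparison of 2 diets in place of an average, so these counts say nothing about stability. Leaving out each library in turn gave 0 to 23 genes for methionine left out, 6 without the normal library, 23 without the combined omission and 20 without the tryptophan/niacin-free library. For tryptophan and niacin left out it gave 0 to 20, 3 without the normal library, 20 without the combined omission and 2 without the tryptophan/niacin-free library. In the fit with 1 mean per diet, leaving out a methionine-free replicate leaves no residual degree of freedom, so that it gives values with no test. All 23, 3 and 43 called genes then kept their sign and at least 2-fold size, with medians of −2.36 and −1.41 in place of −1.96 without replicate 1 and 2, of 3.02 and 1.59 in place of 2.11, and of 3.46 and 3.20 in place of 3.39. These genes were called on the same libraries, and the lone libraries stayed in. Kept signs and sizes were therefore likely in advance and say little about stability. By the size rule on pooled methionine-free counts, 516 genes against normal food became 1364 without replicate 1 and 299 without replicate 2, 719 against the combined omission became 1501 and 387, and 440 against tryptophan/niacin-free food became 1083 and 285.

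Other fold thresholds moved the counts of the size rule by construction, to 878 at 1.5-fold and 37 at 4-fold for tryptophan/niacin-free against normal food, 527 and 13 for the combined omission against normal food, 818 and 49 for the combined omission against tryptophan/niacin-free food and 1562 and 34 between the methionine-free replicates. A prior count of 5 gave 130 genes in place of 202 for the combined omission against normal food. Total-count scaling changed the split between the replicates from 243 higher and 417 lower to 137 and 586, where it moved the median of all genes by −0.113. It moved that median by 0.109 for tryptophan/niacin-free against methionine-free food and by less in the other comparisons. Depth limits what could be seen: a count of 0 gives only a bound from 3 counts, 6.94 CPM in the shallowest library, and 1 to 3 counts give a ratio with a wide interval. IDO1 and CD274 lay under that floor in every library, and NNMT and CHAC1 had at most 9 and 8 counts.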

Other observations

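The tests of length and depth on methionine-free replicate 2 and the correlation between comparisons were chosen after the results were seen, and the count of genes after the length correction was set before its value was seen.

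HSPH1, a co-chaperone of the heat shock response, was at 331 CPM in the combined omission and 278 CPM in the tryptophan/niacin-free library, against 154 CPM on normal food and 170 and 207 CPM in the methionine-free libraries. The co-chaperone CHORDC1 was at 48.6 and 46.3 CPM against 16.7, 21.9 and 24.3 CPM. Neither passed the averaged test (HSPH1 0.83, unadjusted p = 0.00923; CHORDC1 1.25, unadjusted p = 0.00493; adjusted p = 1 for both by edgeR).

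HLA-B stood at 157 and 170 CPM in the methionine-free libraries, against 66.7 CPM on normal food, 86.2 CPM without tryptophan and niacin and 76.3 CPM in the combined omission, and PSMB8 at 53 and 50.2 CPM against 24.1, 20.8 and 41.6 CPM. Neither passed, with edgeR's adjusted p = 0.309 for HLA-B in methionine-free against normal food, and the antigen presentation list, with 0 of 15 members past the threshold over all genes, had an adjusted p = 0.915 with an estimated correlation. The lysosomal amino acid carriers SLC36A1 and SLC38A9 were highest in the combined omission, at 37 and 23.1 CPM, and lowest on normal food for SLC38A9 (5.56 CPM) and in methionine-free replicate 2 for SLC36A1 (3.24 CPM). In these CPM ranges 1 count was worth up to 2.31 CPM.

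Methionine-free replicate 2 stood apart from the 4 other libraries, and transcript length may account for part of it. Its deviation from the mean of the others had a Spearman rho across genes of −0.577 with transcript length (genes are not independent replicates), from a median of 0.50 in the shortest to −0.44 in the longest of 4 groups of genes. Length as the whole cause is argued against only so far as the correction removes its trend. After it 445 genes remained beyond the size rule between both methionine-free replicates, above the 404 of the highest other pair before and 410 after. That excess lies close to the counting spread of 29.1. Against the other diets, which differ in food as well, replicate 2 had 612 to 1012 genes and replicate 1 had 276 to 365. The weight falls on these pairs, a reading added after the values were seen. Sequencing depth is argued against as the cause of the trend with length, though not by thinning. Thinning all libraries to the shallowest total left a rho of −0.55, but thinning keeps each gene's share and could hardly remove such a trend. It replaced a test on the tryptophan/niacin-free library (rho 0.0992), which lay too near its bound to decide. Replicate 2, with 678618 counts, lay in depth between the normal (1088084) and combined-omission (433930) libraries. The combined omission differed from normal food by a median of −0.0157 in the shortest and −0.00706 in the longest group. The trend thus did not follow depth, a reading added after the values were seen. Correction by 1 transcript per gene could leave some of the trend in place, so that what remained may still be a trend with length. RNA quality, which no measure here records directly, stays open.

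A further hypothesis was that both single omissions shift expression alike. The differences of methionine-free from the combined omission and of tryptophan/niacin-free from normal food share no library, and their Pearson r across 8404 genes was 0.208, 0.233 after the length correction, 0.182 with replicate 1 as the only methionine-free library and 0.219 without the hypoxia list. The other pairing of the same 4 diets gave 0.244 (0.28 corrected). Methionine-free against tryptophan/niacin-free with the combined omission against normal food gave −0.0452 (−0.053 corrected). That last covariance is fixed by those of the other pairings, so its value adds no separate evidence. The positive correlations are such as a shared shift of the single omissions would give. A difference in handling between the differently titled libraries would give the same signs, so the diets may not be the source of the shift.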
